A study of Caenorhabditis elegans with 2 samples.

How the data were processed

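Chromatin immunoprecipitation with an anti-GFP antibody was sequenced from 2 biological replicates of early embryos that expressed SEA-1 fused to enhanced GFP; both form 1 group, by the developmental stage in the labels, and take their replicate numbers from the labels. The labels name possible controls, but no control values were used here. The authors deposited narrowPeak lists on assembly ce11, per the labels: a conservative list and a second thresholded list from both replicates, a thresholded list of each replicate's own, and 4 ranked lists. Per the deposited texts that accompany the samples, series lists derive from the alignments of both replicates and own lists from those of 1 replicate, and the thresholded lists used a further input whose role is not stated. The aligner, the peak caller, their versions and the sequencing depth are not given in the sources used here. The depth is therefore unknown and its effect on the number of peaks could not be measured. All values analysed are those of the lists as held here.

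The deposited signal value of each peak is the authors' own, with no normalization stated, and was used only to describe, rank or filter peaks within a list; values from the 2 replicates' lists were set side by side to correlate the replicates and to describe single peaks, and have no stated common scale. The deposited −log10 q-value was read to describe the lists and entered no test. The deposited score in the ranked lists is the −log10 of the irreproducible discovery rate (IDR), a measure of how consistently a pair of peak sets rank a peak; every conservative peak was at 2 or more, an IDR of 0.01, as read from the values. Of the ranked series lists, that which compares the replicates was identified from the files: it held all 1249 conservative peaks past that threshold, and 63.5% of its rows carried the exact coordinates of a ranked peak of replicate 1 and 61.8% of replicate 2, against 996 peaks and at most 0.000963% in the other. The summit was taken from the deposited offset in each peak.

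Positions were set against the WBcel235 sequence and an Ensembl annotation of the same assembly, whose chromosome names and lengths hold every peak. The annotation has 19973 protein-coding gene records under 19865 distinct symbols, over which the gene lists were tested. A promoter window ran from 1000 bp upstream to 200 bp downstream of each annotated transcript 5′ end. Positions are 1-based. Replicates were compared by overlap of at least 50% of the shorter peak and by the signal value of the best ranked peak that overlapped by at least 1 bp. Promoter and noncoding gene shares were tested against 1000 circular shifts of the peaks along their chromosomes, one-sided. The X share was tested by an exact binomial test against the share of protein-coding genes. Gene lists, 29 fixed before the data were examined, were tested by Fisher's exact test with Benjamini-Hochberg adjustment; 3 of their members had no match in the annotation. Motifs were counted on both strands within 100 bp of the summit, with 10 control windows per peak at the same distance from the 5′ end of coding genes without a peak of any thresholded list in the promoter window. The plan had excluded genes with a peak in any list, which the ranked lists made too strict, as 14056 coding genes had a ranked peak. GC-matched controls were 5 windows per peak, except that 3 peaks without enough windows of like GC content had none. All 2080 6-mers were tested by Fisher's exact test with Benjamini-Hochberg adjustment. Loci were compared with 1000 random windows of equal length.

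The genes named were set before the data were examined. They were coding genes whose promoter window held the summit of any of the 20 strongest conservative peaks that overlap both own lists. Named whatever their values were sea-1, unc-119, xol-1, sex-1, ceh-39, fox-1, sex-2, sea-2, her-1 and sdc-2. Of each list, up to 4 bound members of highest signal value were named, or all where there were 5 or fewer. Also named were the 3 strongest peaks found in only 1 own list of each replicate. Noncoding genes, the genes frm-7 and ints-8 whose introns hold peaks, and the chemoreceptor genes str-12 and srt-41 were named after their values had been seen.

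On simulated peaks, a promoter share raised by moving 20% of peaks was found (permutation p = 0.005, the smallest the shifts there can give) and an unmoved set gave p = 0.68. Of lists of 80 genes with a 4-fold share of bound genes 84% were recovered, of lists of 40 genes 50%, and 0.25% of lists without an effect were called. Of 6-mers planted in 5% of peaks 85% were recovered, with none called where nothing was planted. Small lists could therefore miss a 4-fold difference. For the 6-mers, simulated peaks and controls were both drawn at random positions. The absence of false calls there does not cover the difference in GC content between the real peaks and their controls. Alternatives changed the peak list, the promoter window, the overlap rule, the chance model, the motif and the control windows; leaving out a replicate meant using the other's own list. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.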

Results

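SEA-1, a T-box transcription factor known as an autosomal signal element that acts on the sex-determination switch gene xol-1, was profiled by chromatin immunoprecipitation and sequencing in whole Caenorhabditis elegans early embryos (0 hour) obtained by bleaching. The strain carried an integrated sea-1 transgene tagged with enhanced GFP, together with an unc-119(+) rescue marker, and chromatin was sonicated to 200-800 and precipitated with an antibody against GFP. The labels give 1 group with 2 biological replicates and no second condition, so the comparisons are between the replicates, and between the peaks and the positions expected by chance. The values are those of peak lists on build ce11, and the sequencing depth behind them is unknown. The conservative list held 1249 peaks in 1188 separate regions, the second list made from both replicates held 1241, and the replicates' own lists held 536 peaks (replicate 1) and 556 peaks (replicate 2). Of the 1249 conservative peaks, 996 overlapped a peak of the second list, 465 one of the own list of replicate 1 and 475 one of that of replicate 2. Only 328 overlapped peaks of both own lists. The authors' signal value in the conservative list had a median of 95.5, an interquartile range of 81.1 to 129 and a maximum of 791. Of the 48 peaks with a signal value under 20, 47 overlapped a stronger peak of the same list. Intervals are 95% Wilson intervals of counts of peaks or genes and cover counting error only.

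The first question was whether the 2 replicates found the same sites. The strongest conservative sites were found in both. The snoRNA gene W03C9.9, a noncoding RNA gene on chromosome II, lay at the conservative peak of highest signal value (II:11960687-11960966, intergenic), with signal values of 385 in replicate 1 and 399 in replicate 2. The second strongest peak (V:12303505-12303770) lay in an intron of frm-7 beside the snoRNA genes C51F7.3 and C51F7.4, with 386 in replicate 1 and 351 in replicate 2. Of the 536 peaks of replicate 1, 333 (62.1%, interval 57.9 to 66.1) overlapped a peak of replicate 2 by at least 50% of the shorter peak, against a mean of 0.174% and a maximum of 0.933% over 1000 circular shifts (one-sided permutation p = 0.001, the smallest these shifts can give). In the other direction 59.5% of the 556 peaks of replicate 2 overlapped a peak of replicate 1. Across the 1240 conservative peaks with a ranked peak in both replicates, log10 signal values correlated with Pearson's r = 0.80 and Spearman's rho = 0.55 (permutation p = 1e-05 for each, the smallest 100000 permutations can give). Without the 2 peaks farthest from the median r was 0.79. Peaks are not independent replicates, and the list holds peaks chosen because both replicates ranked them alike. Conservative peaks that overlap each other can also share the same ranked peaks, so some pairs of values entered the correlation more than once.

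**Figure D1:**
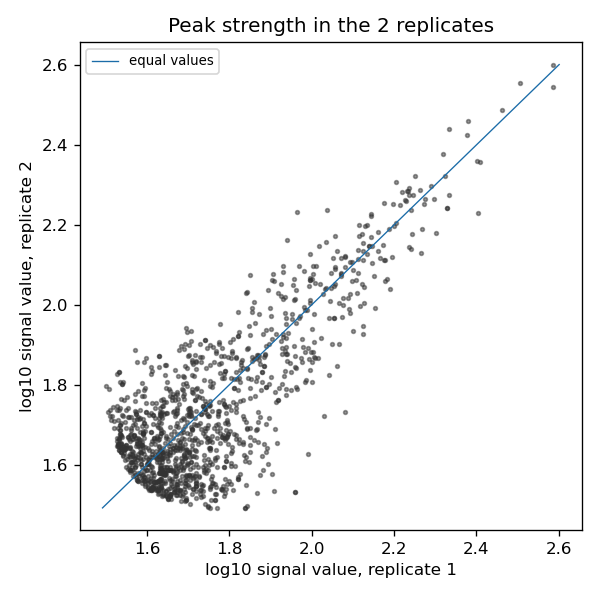
Each point is 1 of the 1240 conservative peaks with a ranked peak in both replicates, and peaks that overlap each other can repeat the same values. The axes are the log10 of the authors' signal value in replicate 1 and in replicate 2, and the line marks equal values. Strong peaks lie along the line and weak ones scatter around it (Pearson's r = 0.80, Spearman's rho = 0.55).

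Peaks found in only 1 replicate's own list were weaker. The 203 such peaks of replicate 1 had a median signal value of 59.3, against 91.6 for its shared peaks, and the 225 of replicate 2 had 56.9 against 92.0. Most had a weaker counterpart in the other replicate's ranked list, by an overlap of at least 1 bp. Of the 203, 195 overlapped a ranked peak of replicate 2, and of the 225, 211 a ranked peak of replicate 1. The ranked lists are long (68844 peaks in replicate 2 and 71678 in replicate 1), and the share expected by chance was not computed. The best overlapping peaks had a median rank of 1379 in replicate 2 and 1404 in replicate 1. Their median signal values were 42.0 and 43.0, against 16.4 and 16.6 in the whole ranked lists. For these peaks as a set, this argues against overlap with random members of the lists. The strongest peak of replicate 2 alone lay in the promoter window of the hedgehog-related gene wrt-3 (IV:9477645-9477928, signal value 137) and had no ranked peak in replicate 1, and the next (III:4689636-4689919, 110; X:5319304-5319587, 103) had none either. The strongest of replicate 1 alone (X:12563644-12563947, 128) had no ranked peak in replicate 2. The next were V:13645953-13646256, with 107 in replicate 1 and 52.6 in replicate 2, and I:9855439-9855742, with 97.8 and 42.2. These 5 peaks lay in no coding promoter window.

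Most of the strongest conservative peaks lay at genes for noncoding RNAs. Of the 20 strongest conservative peaks that overlapped both replicates' own lists, 10 lay within 100 bp of a snoRNA gene, whose products guide RNA modification, and 4 of a tRNA gene. A further peak (I:13463838-13464105, signal value 402) lay at rpr-1, the RNA component of RNase P, in an intron of ints-8, and another (IV:11026076-11026368, 461) at the noncoding RNA gene F36H1.17. In the whole list 222 of the 1249 peaks (17.8%, interval 15.8 to 19.99) lay within 100 bp of a tRNA gene, against 0.180% after circular shifts, a ratio of 98.8, or 43.3 against randomly drawn ranked peaks. The ratio was 52.2 within 250 bp and 291.6 for summits inside the gene. At snoRNA genes lay 61 peaks (4.88%, interval 3.82 to 6.22) against 0.119%, a ratio of 41.1, or 24.3 against randomly drawn ranked peaks, and at snRNA genes 22 peaks (1.76%) against 0.033%. In the own list of replicate 1 the ratio to circular shifts was 148.4 at tRNA genes and 92.8 at snoRNA genes, and in that of replicate 2 it was 145.3 and 79.5. Among 10 noncoding and pseudogene classes tested, these 3, miRNA genes (6 peaks) and the annotation's ncRNA class (289 peaks, many shared with the others) exceeded the shifts, each at an adjusted permutation p of 0.002. Genes for rRNA and antisense RNA had no peak, but the shifts put only 0.012% and 0.118% of peaks there, too few to show a lack of peaks. Genes for lincRNA had 4 (adjusted permutation p = 0.81), and piRNA genes had 2 and pseudogenes 18, both below the shifted mean.

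Seen from the genes, 225 of 612 tRNA genes (36.8%, interval 33.04 to 40.7), 60 of 346 snoRNA genes (17.3%, interval 13.7 to 21.7) and 22 of 129 snRNA genes (17.1%, interval 11.5 to 24.5) had a conservative peak. The replicates gave like numbers for tRNA genes, 155 in the own list of replicate 1 and 152 in that of replicate 2, and for snoRNA genes, 53 and 52, but only 8 and 10 snRNA genes had a peak in those lists. Of the 222 summits at tRNA genes 184 lay inside the gene, and all 222 lay a median of 23 bp downstream of the 5′ end, with 10.4% upstream of it. Summits lay mostly upstream of snoRNA genes, where 50 of 61 summits (82.0%) preceded the 5′ end. The 304 peaks at any of the 3 classes had a median signal value of 147, against 89.5 for the other 945. Among the 125 strongest peaks 44% lay at tRNA genes and 23.2% at snoRNA genes, against 1.61% and 3.23% of the 124 weakest. The share of summits in coding exons went the other way, from 0 of the strongest 125 to 25.8% of the weakest 124. Those weakest 124 hold the 48 peaks with a signal value under 20, of which 47 overlapped a stronger peak of the list. Among the next weakest 125 peaks, 4% lay at tRNA genes, 0 at snoRNA genes and 14.4% in coding exons. These tests were chosen after the strongest peaks had been seen, and many tRNA genes have identical copies among which reads may have been placed at random.

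**Figure D2:**
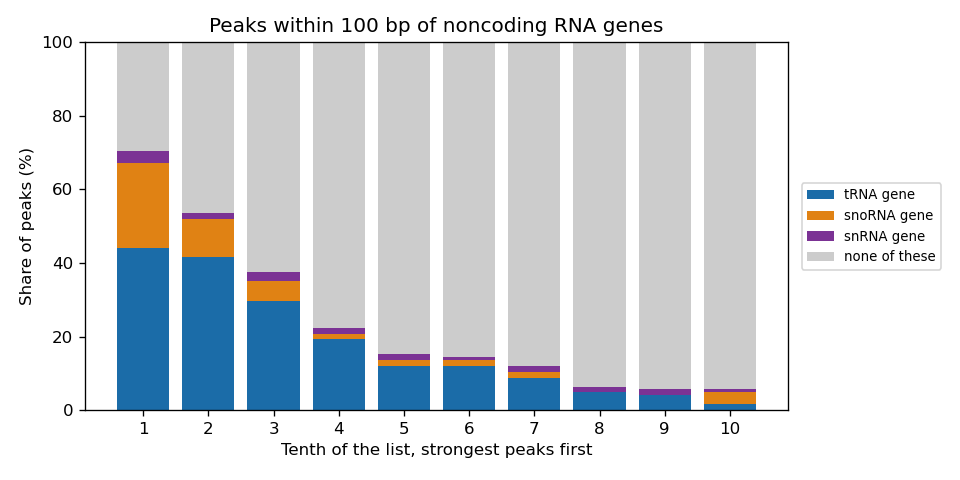
The 1249 conservative peaks are split into 10 parts in order of the authors' signal value (x axis, strongest at the left), and the stacked bars give the percentage of peaks with a summit within 100 bp of a tRNA, snoRNA, snRNA or none of these genes. The share at tRNA genes runs from 44% in the strongest part to 1.61% in the weakest, which holds 47 peaks that overlap a stronger peak of the list.

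Among protein-coding promoters, the strongest peak found in both replicates lay upstream of K12H4.5 (III:8043850-8044101, signal value 597), followed by a peak at the chemoreceptor gene sre-23 and the snoRNA gene ZK265.10 (I:8259437-8259706, 539), and by 1 shared by atx-2, the ataxin-2 homolog, and ecps-1 (III:10461187-10461421, 460). Peaks at T02E1.2 (I:8224308-8224530, 429), at mrps-28, a mitochondrial ribosomal protein gene (V:19643132-19643353, 385), at F55A11.6 and F55A11.11 (V:11782817-11783032, 376) and at the pre-mRNA cleavage factor gene cfim-2 (IV:8927121-8927336, 372) each lay beside a snoRNA gene. Those at the ribosomal protein gene rpl-3 (III:3867481-3867673, 384) and between ears-2 and uncp-18 (IV:390391-390564, 380) lay at no such gene. In all, 529 of 1249 summits (42.4%, interval 39.6 to 45.1) lay from 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding transcript, against 25.7% after circular shifts, a ratio of 1.65 (one-sided permutation p = 0.001, the smallest 1000 shifts can give). By annotation, 379 summits (30.3%) were intergenic within a promoter window against 11.99% after shifts, 378 (30.3%) intronic against 33.7%, 335 (26.8%) intergenic elsewhere against 25.01%, and 115 (9.21%) in coding exons against 24.5%. The 5′ UTRs held 24 summits and the 3′ UTRs 18. Of the intronic summits, 144 lay at tRNA, snoRNA or snRNA genes.

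Histone genes and genes of the translation machinery carried peaks more often than other coding genes, and chemoreceptor genes less often. Of 19865 coding gene symbols, 657 (3.31%) had a conservative summit in the promoter window. Among histone genes 27 of 59 did (odds ratio 25.7, adjusted exact p = 3.26e-23), whose strongest peaks were 17 distinct ones, since paired histone genes share an upstream region. The strongest lay between his-67 and his-68 (I:9988847-9989043, signal value 295, with 157 in replicate 1 and 132 in replicate 2), followed by the linker histone gene hil-3 (X:8159006-8159325, 151) and his-59 (IV:7487697-7488016, 140, a coding exon). Histone genes were not compared by sequence, so reads shared between copies are not excluded. Among ribosomal protein genes 14 of 81 had a peak (odds ratio 6.22, adjusted exact p = 3.72e-06), led by rpl-3 (179 in replicate 1, 209 in replicate 2), rpl-15 (IV:654858-654998, signal value 268), rpl-20 (IV:4749903-4750222, 189) and rps-26 (I:14759345-14759664, 174). Among translation factor genes 7 of 40 had one (odds ratio 6.26, adjusted exact p = 0.00219), led by iff-2 (II:8561273-8561592, 120), eif-3.C (I:9979762-9980081, 114), the elongation factor gene eef-2 (I:9163364-9163683, 105) and eef-1A.2 (X:7823179-7823498, 93.9). Only 6 of 1289 chemoreceptor genes had a peak (odds ratio 0.129, adjusted exact p = 1.86e-11): sre-23, sre-1 (signal value 225), sri-5 (129) and srh-269 (105) led, with str-12 and srt-41. Tests were Fisher's exact tests, two-sided, with Benjamini-Hochberg adjustment over 29 lists. Counted by peaks in place of genes, histone promoters held 11.2 times and chemoreceptor promoters 0.333 times the expected number. Among genes with a ranked peak the odds ratio was 0.201 for chemoreceptors and 4.47 for ribosomal proteins. For ribosomal proteins it was 10.3 with the own list of replicate 1 and 10.1 with that of replicate 2, and counted by peaks 4.41 times the expected number. The translation factor call was lost with the own list of replicate 2 alone (2 genes, odds ratio 3.29, adjusted exact p = 0.545). It was also lost with that of replicate 1 alone (3 genes, 5.19, adjusted exact p = 0.139) and in the stronger 624 peaks (3 genes, 4.04, adjusted exact p = 0.161). Peaks that overlapped both own lists belonged to 11 of the 27 histone genes and 8 of the 14 ribosomal protein genes. They belonged to 1 of the 7 translation factor genes and 3 of the 6 chemoreceptor genes.

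The other 25 lists did not pass. Of 39 mitochondrial respiration genes 5 had a peak (odds ratio 4.32, adjusted exact p = 0.0514), namely cox-6A (signal value 213), cox-5B (164), cox-6B (125), the cytochrome c gene cyc-2.1 (82.8) and nuo-2 (75.4). Of 59 cell cycle genes 6 had one (adjusted exact p = 0.0631), led by the centrosome and centriole genes spd-5 (259), sas-5 (166) and sas-4 (119.2) and by the retinoblastoma homolog lin-35 (108). Of 31 maternal polarity and cell fate genes 4 had one (adjusted exact p = 0.0761): the RNA-binding protein genes mex-1 (117), spn-4 (102) and mex-3 (81.5) and the kinase gene lit-1 (87.2). Heat shock genes had 3 of 21 (adjusted exact p = 0.111), hsp-1 (166), hsp-60 (159) and hsp-3 (118.7). F-box genes had 4 of 315 (adjusted exact p = 0.122), fbxb-85 (113), fbxb-58 (90.1), fbxc-44 (89.9) and fbxa-153 (78.1), and C-type lectin genes 3 of 237 (adjusted exact p = 0.278), clec-126 (184), clec-53 (86.4) and clec-264 (64.7). The remaining 19 lists had adjusted p-values from 0.610 to 1. Sex determination had 2 of 28, the helicase genes mog-5 (99.7) and mog-4 (89.2). Dosage compensation had 1 of 16, the histone methyltransferase gene set-4 (78.4), and T-box genes 1 of 21, tbx-2 (82.0), which was also the only 1 of 28 pharynx genes. None of the peaks of mog-5, mog-4, set-4 and tbx-2 overlapped both own lists, and that of set-4 had no ranked peak in replicate 1. Notch and Wnt genes had 2 of 38, mom-1 (367) and lit-1; hypodermis 2 of 31, ajm-1 (113) and dpy-17 (78.7); and germline 2 of 48, egg-5 (248) and spn-4. Collagens had 2 of 156, col-185 (232) and col-71 (99.8), detoxification genes 2 (1.79%), gst-27 (187) and ugt-40 (86.9), and proteasome genes 2 of 33, rpn-7 (115) and pbs-3 (80.1). Nuclear hormone receptors had 6 of 269, led by nhr-255 (286), nhr-141 (173), nhr-41 (148) and nhr-48 (91.6). Neuronal genes had 1 of 40, syd-2 (148), homeobox ceh genes 1 of 63, ceh-13 (91.9), and GATA factors 1 of 12, egl-27 (118.6). Lineage specification (39 genes), body wall muscle (36), intestine (29), bHLH (25) and insulin signalling (48) had 0, where counts this low were within chance. Of the genes named in these lists, the peaks of mom-1, egg-5, ajm-1, col-185, gst-27, ugt-40, nhr-255, nhr-41, clec-126, cox-6A, rps-26, srh-269 and sre-23 lay within 100 bp of a tRNA, snoRNA or snRNA gene.

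The X chromosome was examined because SEA-1 takes part in counting X chromosomes against autosomes. X held 270 of 1249 peaks (21.6%, interval 19.4 to 24.0), against 13.7% of protein-coding genes (two-sided exact binomial p = 2.31e-14), 17.7% of the length of the nuclear chromosomes (p = 0.000364, same test) and 16.2% of weaker ranked peaks (p = 5.56e-07). X also held 276 of the 612 tRNA genes (45.1%) and 99 of the peaks at tRNA genes. Among the 304 peaks at tRNA, snoRNA or snRNA genes 100 (32.9%) were on X, and among the other 945 peaks 170 (17.99%, interval 15.7 to 20.6). The latter share exceeded that of coding genes (exact binomial p = 0.000214) but not that of length (p = 0.798) or weaker ranked peaks (p = 0.133). Chromosome III had the most peaks per megabase away from these genes (13.4, against 9.59 on X), and chromosome V the fewest (6.31).

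**Figure D3:**
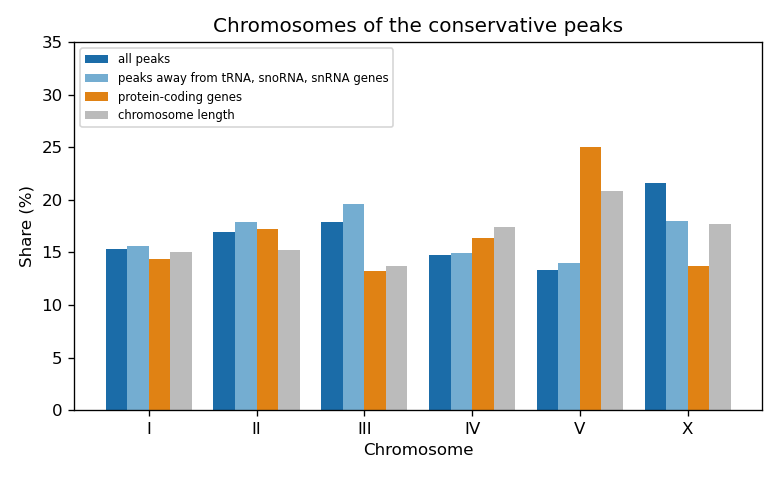
For each chromosome (x axis) the bars give the percentage of all conservative peaks, of peaks farther than 100 bp from tRNA, snoRNA and snRNA genes, of protein-coding genes and of chromosome length. X holds 21.6% of all peaks and 17.99% of those away from these noncoding genes, beside 17.7% of the length.

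The T-box core GGTGTGA, the sequence that T-box domains are known to bind, was not significantly more frequent at the peaks than in control windows at like distances from unbound genes. It occurred within 100 bp of 20 of 1249 summits (1.60%, interval 1.04 to 2.46) and in 1.23% of 12490 control windows (odds ratio 1.304, interval 0.815 to 2.08; Fisher's exact p = 0.286, two-sided). Against GC-matched controls the direction turned, with 2.44% in the controls (Fisher's exact p = 0.0782). The shorter core GTGTGA occurred at 8.97% of peaks against 7.31% of the 12490 control windows (Fisher's exact p = 0.0366), a difference that did not pass adjustment over the 2080 6-mers (adjusted exact p = 0.0519) and turned against GC-matched controls (odds ratio 0.929, adjusted exact p = 0.644). The other 6-mer of the core, GGTGTG (CACACC on the other strand), occurred at 9.77% of peaks against 4.27% of the same unmatched windows. Its odds ratio of 2.43 passed that adjustment (adjusted exact p = 3.01e-14). Against GC-matched controls it was 1.19 and did not pass (adjusted exact p = 0.171). Among the 945 peaks away from tRNA, snoRNA and snRNA genes the share of GGTGTGA was 2.01% against 1.09% (Fisher's exact p = 0.0171), but ranked peaks of like GC content held it in 2.35% (Fisher's exact p = 0.634), comparisons chosen after seeing the data. Peaks with the core had a median signal value of 90.4 and those without it 95.7 (permutation p = 0.545). Among all 2080 distinct 6-mers, 1460 differed between peaks and controls at an adjusted Fisher's exact p under 0.05, of which 852 (58.4%) were more frequent at peaks. The peaks were richer in G and C (median 46.8%) than the controls (34.8%), and against 5 GC-matched controls per peak 879 differed, of which 402 (45.7%) were more frequent at peaks. Among 6-mers found in at least 5% of peaks, the leading ones were GC-rich: CCCGGG (6.16% of peaks, odds ratio 9.94), GCGCGC (11.6%, 9.14), CGCACG (12.2%, 8.05), CGCGCG (8.25%, 7.44) and GCGCAC (15.6%, 7.06), followed by CGAACC (17.9% of peaks against 3.11% of controls, 6.78), CGCGCA (15.7%, 6.73), CCCGCG (8.81%, 6.68), CCCCGC (13.2%, 6.61) and CGGCCC (8.17%, 6.33). CGAACC, which on the other strand reads GGTTCG as in the B box of tRNA genes, an internal promoter element, had the highest odds ratio (3.84) of these common 6-mers against GC-matched controls. There the odds ratio was 3.53 for CGCACG, 3.43 for CCCGGG, 3.34 for GCGCAC, 3.15 for CGCGCA and 2.81 for GCGCGC, and the other 4 were not among the 10 highest. At the 945 peaks away from tRNA, snoRNA and snRNA genes, CGAACC was not among the 10 highest against controls not matched on GC. GCGCGC (odds ratio 10.1), CGCACG (7.51) and CGCGCA (7.50) led there, in a comparison chosen after seeing the data.

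No gene of the X signal pathway had a conservative peak in its promoter window. At xol-1 (X:8041313-8044409, with 2000 bp upstream) the best peak in the ranked list that compares the replicates had a signal value of 34.2 and rank 28078 of 104066, which put xol-1 at the 35.9th percentile of coding genes. In replicate 1 it was at the 70.4th percentile and in replicate 2 no ranked peak was listed. A conservative peak (X:8036631-8036950, signal value 127) lay 4522 bp upstream of xol-1, at a tRNA gene. The X signal element genes ceh-39, sex-1 and fox-1 were at percentiles 91.1, 89.1 and 79.8, sea-2 at 87.5, sdc-2 at 65.2 and her-1 at 58.5. The percentile of sdc-2 was 77.5 in replicate 1 and 37.3 in replicate 2. Each percentile ranks the best ranked peak anywhere in the gene and 2000 bp upstream, with no correction for gene length. Longer genes, such as sea-2 (II:3950377-3972140) and fox-1 (X:2445117-2459893), can hold more ranked peaks than xol-1. The percentiles are therefore not comparable measures of binding between these genes. With 5000 bp upstream xol-1 was at the 96.7th percentile, by the peak at the tRNA gene, and ceh-39 at the 98.7th, with a signal value of 220.5. The annotation used had no coding gene named sex-2.

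The transgene's own loci were compared with random windows because extra copies can change read density. No ranked peak lay within 20 kb of sea-1 (II:3651908-3693593) in any of the 4 ranked lists, where random windows of that length held a median of 47 in the list that compares the replicates, and 8 of 1000 held none. The stretch without a ranked peak ran over 53.2 kb (II:3645906-3699134), and 32 stretches of the genome in that list were at least as long. Around unc-119 (III:10882641-10928935) lay 64 ranked peaks against a median of 51, and 790 of 1000 random windows held as many or fewer. The best peak at unc-119 itself had a signal value of 70.2, at the 90.1th percentile of coding genes, also without a correction for gene length.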

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

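The test of the X share away from noncoding genes and the comparison of tRNA genes on X and autosomes were chosen only after the results had been seen; those of identical copies and of GC content at tRNA genes were set before.

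Signals outside the analysed list were found among ranked peaks: of 1368 peaks past the IDR threshold, 1249 were in the conservative list and 8.70% were not. The strongest of those left out had a signal value of 2926 (X:15810941-15811207), and 3 exceeded the strongest conservative peak. A median of 98.8% of their bases were soft-masked repeats in the reference, against 19.7% for conservative peaks, and 0 lay at a tRNA, snoRNA or snRNA gene. There were no control samples here to set these values against.

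Strong peaks at tRNA genes were weighed against reads shared between identical copies. Of the 140 tRNA genes whose whole sequence occurs once in the genome, 22.9% had a peak (interval 16.7 to 30.5). This argues against reads shared between wholly identical copies as the whole cause, although genes with several copies had peaks more often (40.9%, Fisher's exact p = 9.16e-05). Reads shared between genes that differ by a few bases were not measured, so sharing of that kind stays open. GC content as the whole cause was argued against too: among ranked peaks of like GC content, those at tRNA genes were in the conservative list with a Mantel-Haenszel odds ratio of 70.0 (interval 55.5 to 88.3). Enrichment of any tagged protein or of open chromatin at highly transcribed genes stays open, since no other factor and no untagged strain were analysed here. No biological explanation was tested.

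The excess of peaks on X was weighed against the concentration of tRNA genes there. Away from tRNA, snoRNA and snRNA genes the X share was 17.99% (interval 15.7 to 20.6), which holds the 17.7% expected by length, so these genes may account for the excess over length. They do not account for the whole excess over the 13.7% of coding genes, which lies below that interval. The tRNA genes on X had a peak in 35.9% of cases and those on autosomes in 37.5% (Fisher's exact p = 0.736). No biological explanation was tested.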

How the results depend on the processing

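Alternatives that used merged regions, a signal value of at least 20, or peaks away from tRNA, snoRNA and snRNA genes, and all tests of tRNA and snoRNA gene peaks, were chosen after seeing the data. No paired analysis was possible because there is a single group. Replicate overlap (59.5% to 78.4%), replicate correlation (r from 0.67 to 0.80), promoter share (31.1% to 59.2%), tRNA gene peaks (14.7% to 29.3%) and snoRNA gene peaks (0.721% to 10.6%) kept their direction and their side of the threshold under every alternative run. The X share fell to 17.99% away from the noncoding genes and no longer exceeded length or weaker ranked peaks there. By construction the stronger part of the list held 624 peaks. With windows from 2000 bp upstream to 500 bp downstream 9 gene lists passed in place of 4; the cause was not tested. The T-box core share became significant away from the noncoding genes (2.01%, Fisher's exact p = 0.0171) and for the shorter GTGTGA (8.97%, exact p = 0.0366, but odds ratio 0.929 against GC-matched controls). The GGTGTGA share fell below the controls in the stronger part of the list (1.12%, 7 of 624 peaks, Fisher's exact p = 0.854). It also did so against GC-matched controls (1.60% against 2.44%) and against weaker ranked peaks (1.60% against 1.67%). Away from the noncoding genes it did so against ranked peaks of like GC content (2.01% against 2.35%), a test chosen after seeing the data. Using the own list of a single replicate it was 0.719% to 1.12%, below the controls in both. With 5 GC-matched controls per peak 879 6-mers differed in place of 1460, and with 5 unmatched controls, added after seeing the data, 1435. The difference in signal value between peaks with and without the core was -5.32 in the main list and 0.498 away from the noncoding genes. With a single replicate it rested on few peaks with the core. It was -9.20 in replicate 1 (6 peaks, permutation p = 0.506) and 21.3 in replicate 2 (4 peaks, permutation p = 0.218). The xol-1 percentile was 96.7 with 5000 bp upstream, which takes in the tRNA gene peak. The sea-1 window held 58 ranked peaks with 50 kb on each side and 0 in the gene alone. As few were held by 125 and 252 of 1000 random windows there, against 8 of 1000 with 20 kb on each side. The cause of the other changes was not tested. With a single replicate's list, X share ran from 23.3% to 24.3%, promoter share from 43.7% to 45.7%, tRNA gene peaks from 27.2% to 28.5% (17.8% in the main list), snoRNA gene peaks from 9.35% to 10.6% (4.88%), 6-mers that differed from 1147 to 1217, and 3 gene lists passed.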

Other observations

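The tests of chance placement and of transgene copies at sea-1, and the count of long stretches without a ranked peak, were chosen after the result had been seen; the others were set before, except that the requirement on the interval in the U6 test was added after its value had been seen.

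A tRNA-like B box (GTTCGA, then any 2 bases and C) was counted within 100 bp of the summits. It occurred at 73.0% of peaks at tRNA genes, at 27.9% of the 61 peaks at snoRNA genes (interval 18.2 to 40.2), at 2.65% of the 945 other peaks and at 1.84% of weaker ranked peaks. The share at snoRNA genes exceeded that of weaker ranked peaks (Fisher's exact p = 1.62e-15), and stayed below the 50% set beforehand for the B box as the main feature of these peaks. The pattern was found at only 73.0% of peaks at tRNA genes, so it may miss B boxes, and the share at snoRNA genes may be too low. Whether a B box accounts for part or most of the snoRNA gene peaks was therefore not settled. Peaks at genes of the annotation's ncRNA class and at no tRNA, snoRNA or snRNA gene numbered 118, of which 8 were among the 125 strongest.

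Whether the peaks follow RNA polymerase III was asked at snRNA genes, where U6 genes are transcribed by that polymerase and other snRNA genes by polymerase II. Of 22 U6 genes 5 had a peak and of 107 other snRNA genes 17, a difference of 6.84 percentage points (interval -8.14 to 28.3; Fisher's exact p = 0.533). The bound set beforehand against the hypothesis, a difference under 10 points, was met by the value itself. The interval reaches past that bound and past 0, so with these counts the hypothesis stays open.

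For the absence of ranked peaks around sea-1, chance placement is argued against only at 20 kb on each side, where 0.8% of random windows held as few. With 50 kb on each side 125 of 1000 did, for the gene alone 252 of 1000, and 32 stretches of the genome without a ranked peak were at least as long. Low GC content is argued against, since the window's GC content, 37.3%, was above that of 86.2% of random windows. Of 4589 windows of like GC content 0.414% held none, but as these are not low in GC, that test does not bear on low GC content. Repeats are argued against too, since 28.6% of the window was soft-masked, below the median of 32.8%. Extra transgene copies in the background reads may lower peaks there, but unc-119, named in the same transgene, held 10 ranked peaks against a median of 7, and as the labels do not state which species' unc-119 was used, this cannot be told apart, and a region left out at any step before these lists also stays open. Of 154 stretches of 30 kb or more without a ranked peak in the list that compares the replicates, 7 were empty in all 4 lists, among them that of sea-1 (GC content 36.7%) and 3 on V (37.6%, 37.4% and 41.2%), while the other 3, on IV, V and X, had a GC content of 29.1%, 33.6% and 30.5%.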
